A study of Mus musculus with 40 samples.

How the data were processed

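The series measured messenger RNA in hypothalami dissected from mice that carry the Aldh1l1-eGFP-L10a transgene, which puts a green fluorescent tag on the ribosomal protein L10a in astrocytes, the support cells that express Aldh1l1. Translating ribosome affinity purification (TRAP) pulls down the tagged ribosomes with the messages bound to them. Each tissue sample gave a pull-down library, labelled IP, and a library of what the pull-down left behind, labelled SN for supernatant. Per the labels, mice ate chow or a high-fat diet (HFD) for 4 weeks, and some were orchiectomised, that is, their testes were removed; the labels write GDX or ORX for this and sham for the control operation. The 3 treatment groups were sham on chow (7 samples), sham on HFD (6 samples) and orchiectomised on HFD (7 samples), each in both fractions, so that 40 libraries entered. No orchiectomised group on chow was analysed here, so an effect of orchiectomy was compared on HFD only. Groups and sample numbers were taken from the labels. The labels do not say whether 1 number is 1 mouse, and p-values measure the spread between these samples.

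Per the labels' protocols, polyadenylated RNA was isolated on oligo-dT beads and made into libraries with the QuantSeq 3' FWD kit, which gives 1 tag near the 3' end of a message, so the number of tags depends little on gene length. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and Salmon 1.9.0 and the genome build GRCm38 were used. The annotation, the strand setting and the way transcripts were summed to genes are not given in the sources used here. The count table deposited by the authors holds estimated counts per gene for 26792 gene symbols, and 12.7% of the non-zero values are not whole numbers. Salmon shares out reads that match several transcripts, so genes with near-identical copies are uncertain: this holds for H2-K1, H2-D1 and H2-T23, for ribosomal protein genes with processed pseudogenes, and for Pcdhgc3, whose last exons are shared by the protocadherin gamma cluster. PCR copies cannot be told from separate molecules in such a table, so the spread between samples, not the number of reads, sets the error of every value.

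A second table, deposited by the authors and named TPM, holds a signal that is not normalised by length. For 25089 of the 26783 symbols in both tables its values equal the estimated counts times 1 factor per library, within 0.01 counts, and 1694 symbols differ, such as App with a summed count of 222689 against 1041 recovered from that table. Its columns sum to between 847343 and 1025286, and 89.4% of its values come back as whole reads. It was used only for alternative tests.

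Counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr (minimum count 10) and a robust fit. The 20 pull-down libraries and the 20 supernatant libraries were fitted apart, each with 3 group means, and all 40 libraries were fitted together with 6 group means for the comparison of the fractions and for the fraction interactions, which test whether an effect differs between pull-down and supernatant. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes came from the F statistic. Values per library are counts scaled to a common library total by TMM (CPM), given as mean ± SD.

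For the named genes the rule was this: of the genes past the threshold with a mean of at least 5 CPM and a regular symbol, the 12 with the smallest p in each direction (by size of change between the fractions), or, where none passed, the 3 with the smallest p in each direction; up to 4 members with the smallest p of each gene list that passed; and Aldh1l1, Gfap, Esr1, Kiss1, Agrp, Npy and Pomc in every case. Kiss1 was not analysed here. Some genes that this rule names are not reported here, and the counts of single-gene fits and of flagged samples leave them out, while all fits and lists contain them. Positions are those of GENCODE M21 on GRCm38, in which 25300 symbols (94.4%) were found.

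Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with at least 5 tested genes, and adjusted over the lists of 1 comparison. Of 37 lists, 13 held cell type markers and 24 held functions; 723 of their 727 genes were in the count table, and 51 genes stood in more than 1 list, among them 11 of the astrocyte markers. The lists of choroid plexus and pituitary markers had 4 tested genes each among all libraries, too few for a result. Counts of list members past the threshold are given over all genes tested and, where they differ, adjusted over the list alone. With a correlation estimated from the residuals in place of the preset value, no list passed in any of the 7 comparisons. The estimated-correlation p therefore stands beside each list named. The astrocyte markers between the fractions, all higher in the pull-down, also failed that test. A failure alone thus does not show that a list is unchanged.

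The designs, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter or a mean of at least 5 CPM, leaving out mitochondrial genes, limma on log2 of the TPM-named signal with a pseudocount of 1 or 0.1, a minimum fold, fits of 2 groups or of all 40 libraries, covariates for neuron markers and total count, the sample number as a block, and fry, which tests whether a list moves one way without comparing it with other genes. After seeing the data, fits without 4 pull-downs, without 1 supernatant library and with covariates for Gm42418 or mt-Rnr2 were added.

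A supernatant is what a pull-down leaves of 1 lysate, so equal numbers were taken to pair the fractions of 1 tissue sample. Deviations from the group means of same-numbered libraries had a median correlation of 0.0326 (lowest −0.0688, highest 0.153), against 0.00328 for differently numbered libraries. In 5 of 20 pairs it was over 0.1, and 6 of the 20 pull-downs correlated best with the supernatant of their own number. No pair of libraries of 1 group agreed within sampling noise: chi-square per degree of freedom over genes was between 4.35 and 234.

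The tests were tried on simulated counts in which 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold at once. The adjusted threshold is stricter where few genes are called, so a lone change would be found less often than given here. At a 2-fold change, edgeR recovered 95.5% of changed genes between the fractions; 67.2% for diet, 77.6% for orchiectomy on HFD and 89.6% for both together in the pull-down; 79.1%, 82.1% and 65.7% for these in the supernatant; and 52.2% and 50.7% for the diet and orchiectomy interactions. At a 1.5-fold change, recovery was 43.3%, 44.8% and 53.7% in the pull-down and 35.8%, 38.8% and 26.9% in the supernatant. False calls by edgeR were 3 of 181 between the fractions; 11 of 149, 9 of 155 and 9 of 167 in the pull-down; 3 of 143, 9 of 154 and 4 of 131 in the supernatant; and 4 of 106 and 7 of 99 for the interactions. For orchiectomy in the pull-down, DESeq2 made 21 false calls of 179 and limma voom 8 of 149. A list raised 1.5-fold was found by camera with both kinds of correlation. Of the 34 other lists, 1 was called with the preset correlation and 0 with an estimated one. Simulated genes were drawn independently of each other, so this does not cover lists whose genes vary together. When the real samples were regrouped at random, the preset correlation called a median of 4 to 8 lists per treatment comparison.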

Results

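Hypothalamic astrocyte messages were measured in 20 pull-down and 20 supernatant libraries of male mice. Sham mice on chow gave 7 libraries per fraction, sham mice on HFD gave 6 and orchiectomised mice on HFD gave 7. Total counts lay between 7714803 and 20792147 in the pull-downs and between 8739269 and 12931843 in the supernatants. Mean totals in the pull-downs were 12070729.7 for chow, 12869776 for HFD and 11191508 for orchiectomised mice. In the supernatants they were 9852332, 9803174 and 10735408. The Y-linked gene Ddx3y had 127 ± 9.14 CPM in the pull-downs and 83.8 ± 8.31 CPM in the supernatants (SD, n = 20 each).

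Mitochondrially encoded messages, which astrocyte cytosolic ribosomes do not translate, took 0.643% to 1.63% of the counts in the pull-downs and 19.2% to 27.8% in the supernatants. Gm42418, an RNA gene on chromosome 17 (39846958 to 39848788, GRCm38) that overlaps a ribosomal RNA repeat, took 1.07% to 18.2% of the pull-down counts. In the supernatants it took 0.127% to 3.67%. It exceeded 10% in 4 pull-downs: sham on chow 8, sham on HFD 1, and orchiectomised 11 and 22. Its mean share was 4.76% in the chow, 5.44% in the HFD and 7.67% in the orchiectomised pull-downs. None of the 132 exact permutation tests of such library measures between groups passed adjustment (lowest exact p = 0.0256, lowest adjusted p = 0.938, two-sided).

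Which messages the astrocyte pull-down enriched was asked first. Astrocyte genes dominated it: Aldh1l1 was higher than in the supernatant by a log2 fold change of 4.89 ± 0.24 (SE, 20 libraries each), and Gfap, the astrocyte intermediate filament, by 4.78 ± 0.15. Slc4a4, a bicarbonate transporter (5.57 ± 0.30), Slc1a2, the main astrocyte glutamate transporter (5.31 ± 0.20), Aqp4, the astrocyte water channel (5.04 ± 0.24), and the receptors S1pr1 (5.38 ± 0.22) and Ednrb (5.24 ± 0.24) were among the most enriched. Eva1a (5.11 ± 0.17), Prex2 (5.07 ± 0.25), Plpp3 (5.05 ± 0.27) and Sdc4 (5.03 ± 0.27) followed. Alb, the serum albumin gene, was also higher (5.29 ± 0.81), with a wider error. The most depleted were mitochondrial transcripts, with mt-Cytb at −5.92 ± 0.13, mt-Nd4 at −5.81 ± 0.15, mt-Atp6 at −5.46 ± 0.14, mt-Co2 at −5.06 ± 0.10, mt-Nd3 at −4.93 ± 0.10 and mt-Nd2 at −4.87 ± 0.18. They were joined by genes of neurons: Hpca, a neuronal calcium sensor (−5.49 ± 0.12), Slc17a7, a vesicular glutamate transporter (−4.99 ± 0.23), and Slc30a3, a synaptic zinc transporter (−4.87 ± 0.18). Lrrc17 (−5.37 ± 0.19), A2ml1 (−5.32 ± 0.19) and Smim18 (−4.82 ± 0.17) fell as far.

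With edgeR, 13561 of 15629 genes (86.8%) differed between the fractions, 6735 higher and 6826 lower in the pull-down. Of these, 3562 were at least 2-fold higher and 4057 at least 2-fold lower, and 666 and 1217 passed 8-fold. TMM scaling takes most genes as unchanged, so the even split and the signs of small changes hold relative to that scaling. The simulated counts, in which few genes changed, do not cover this case. Pcdhgc3 had a fitted log2 fold change of 9.08 ± 0.52, which is no firm size because it was at 0 in the orchiectomised supernatants. Gvin1 was at 0 in every supernatant, against 11.3 ± 21.3 CPM in the chow (n = 7), 4.52 ± 11.1 CPM in the HFD (n = 6) and 24.2 ± 31.8 CPM in the orchiectomised pull-downs (n = 7). The oestrogen receptor Esr1 (−2.29 ± 0.11), Npy (−2.47 ± 0.12) and Agrp (−1.27 ± 0.29, adjusted p = 0.000142), the last 2 being feeding peptides of arcuate neurons, were lower in the pull-down. Pomc, the melanocortin precursor, did not differ (0.22 ± 0.19, adjusted p = 0.274).

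Marker lists separated by cell type. All 22 astrocyte markers rose in the pull-down, with a median log2 fold change of 4.37 (camera adjusted p = 9.19e-10, and adjusted p = 0.226 with an estimated correlation). Examples were Glul, the glutamine synthetase (3.30 ± 0.09), S100b (3.39 ± 0.11) and Clu (3.57 ± 0.13). All 21 neuron markers fell, with a median of −3.48 (camera adjusted p = 9.19e-10, and adjusted p = 0.173 with an estimated correlation). Among these were Stmn2 (−3.86 ± 0.09), Slc32a1, the vesicular GABA transporter (−4.59 ± 0.11), and Rbfox3 (−4.13 ± 0.11). Of 22 hypothalamic neuropeptide genes 21 fell, with a median of −2.77 (camera adjusted p = 4.17e-06, and adjusted p = 0.244 with an estimated correlation). They included Sst (−4.65 ± 0.16), Adcyap1 (−4.38 ± 0.13) and Pmch (−4.10 ± 0.15). All 14 oligodendrocyte markers fell, with a median of −3.53 (camera adjusted p = 2.16e-06, and adjusted p = 0.173 with an estimated correlation). Mbp, a myelin gene, had −3.72 ± 0.12. All 16 microglia markers fell too, with a median of −2.43 (camera adjusted p = 1.17e-05, and adjusted p = 0.208 with an estimated correlation). Examples were Siglech (−3.92 ± 0.14) and Tmem119 (−3.79 ± 0.15). Endothelial markers went the other way: 12 of 13 rose and 1 fell, with a median of 1.86 (camera adjusted p = 0.00616, and adjusted p = 0.421 with an estimated correlation). The members with the smallest p included Flt1 (3.12 ± 0.22), Cdh5 (2.91 ± 0.21) and Slc2a1, the blood-brain barrier glucose transporter (1.83 ± 0.11).

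**Figure D1:**
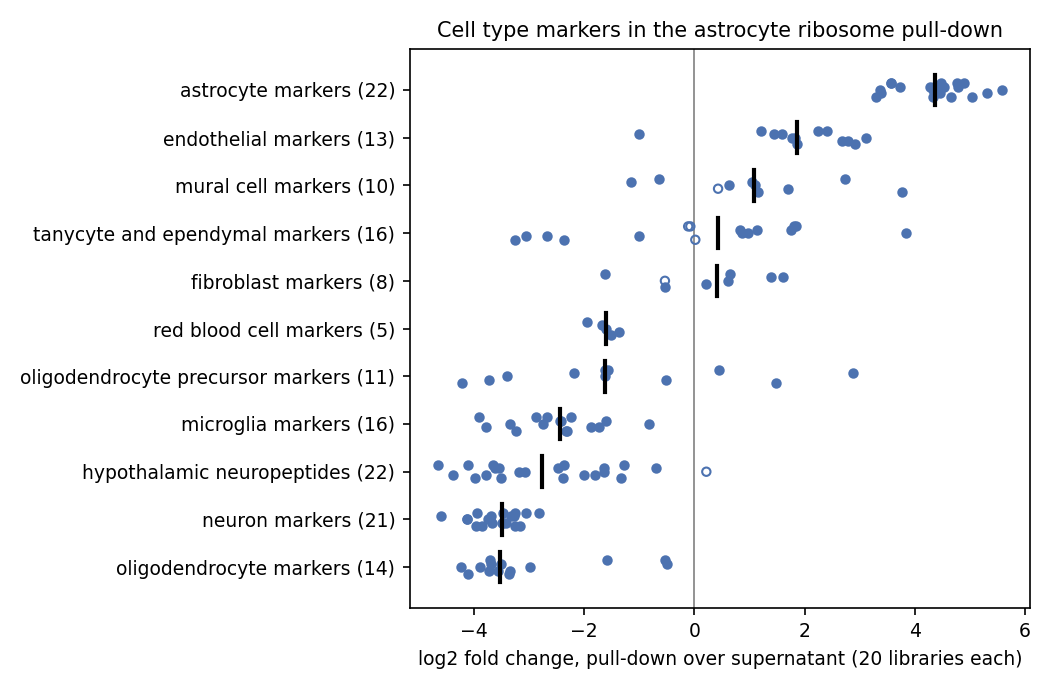
Log2 fold change of each marker gene between pull-down and supernatant (horizontal axis, 20 libraries each), by cell type list; filled points passed edgeR's adjusted p, open points did not, and black bars are list medians. Astrocyte markers lie to the right with a median of 4.37, endothelial markers have a median of 1.86, and neuron and oligodendrocyte markers lie to the left with medians of −3.48 and −3.53.

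The other marker lists did not pass camera: oligodendrocyte precursors (median −1.61, adjusted p = 0.115, and adjusted p = 0.242 with an estimated correlation), mural cells (1.07, adjusted p = 0.138, and 0.505 with an estimated correlation), red blood cells (−1.61, adjusted p = 0.138, and 0.558 with an estimated correlation), fibroblasts (0.41, adjusted p = 0.557, and 0.752 with an estimated correlation), and tanycytes and ependymal cells (0.42, adjusted p = 0.456, and 0.567 with an estimated correlation). Within them, 8 of 11 precursor markers fell and 3 rose, and all 5 red blood cell markers fell. Of 10 mural cell markers 7 rose and 2 fell, of 8 fibroblast markers 5 rose and 2 fell, and of 16 tanycyte and ependymal markers 8 rose and 5 fell. Adjusted over the list alone, the numbers were the same, except that 3 fibroblast markers fell.

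Among functions, genes for the uptake and metabolism of transmitters and ions rose in the pull-down: 19 of 20, with a median of 3.91 (camera adjusted p = 8.03e-08, and adjusted p = 0.208 with an estimated correlation). Among these was Abat, the GABA transaminase (2.84 ± 0.06). Of 21 genes of fatty acid oxidation 20 rose, with a median of 2.72 (camera adjusted p = 8.03e-08, and adjusted p = 0.122 with an estimated correlation). They included Cpt1a, the mitochondrial entry step (4.21 ± 0.12), and Hadhb (3.15 ± 0.09). Fatty acid synthesis rose in 13 of 15 members, with a median of 2.81 (camera adjusted p = 9.35e-05, and adjusted p = 0.187 with an estimated correlation), with Srebf1 at 3.39 ± 0.10 and Scd2 at 3.34 ± 0.09. Cholesterol synthesis rose in 15 of 24 members and fell in 4, with a median of 0.49 (camera adjusted p = 0.0397, and adjusted p = 0.359 with an estimated correlation), and lipid transport and storage rose in 15 of 22 and fell in 5, with a median of 1.57 (camera adjusted p = 0.0131, and adjusted p = 0.242 with an estimated correlation). The fatty acid binding proteins of the latter split, with Fabp5 at 1.93 ± 0.06 and Fabp3 at −4.28 ± 0.13. Antioxidant and metallothionein genes rose in 18 of 21 members, with a median of 1.76 (camera adjusted p = 0.000278, and adjusted p = 0.122 with an estimated correlation). The members with the smallest p included Mt1 (3.94 ± 0.16) and Cat, the catalase gene (2.62 ± 0.09).

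All 16 NF-kB and cytokine genes rose, with a median of 1.16 (camera adjusted p = 0.000918, and adjusted p = 0.116 with an estimated correlation). Vcam1, an adhesion molecule gene, had 3.99 ± 0.14. Interferon response genes rose in 18 of 20 cases, with a median of 1.68 (camera adjusted p = 0.000112, and adjusted p = 0.187 with an estimated correlation). Ifit3 had 3.24 ± 0.11. Class I antigen presentation rose in 11 of 14 members, with a median of 1.64 (camera adjusted p = 0.0086, and adjusted p = 0.304 with an estimated correlation). B2m, the light chain of class I molecules, had 2.36 ± 0.08. Genes of astrocyte reactivity rose in 23 of 28, with a median of 1.42 (camera adjusted p = 0.000507, and adjusted p = 0.187 with an estimated correlation), and extracellular matrix genes in 16 of 22, with a median of 1.91 (camera adjusted p = 0.00492, and adjusted p = 0.226 with an estimated correlation). Among these were Timp3 (3.57 ± 0.09) and Ncan (3.72 ± 0.12). Glucocorticoid response genes rose in 12 of 17, with a median of 1.17 (camera adjusted p = 0.0169, and adjusted p = 0.226 with an estimated correlation). Hypoxia genes rose in 13 of 18, with a median of 1.16 (camera adjusted p = 0.0181, and adjusted p = 0.187 with an estimated correlation). Epas1, a hypoxia-inducible factor gene, had 3.30 ± 0.08. Circadian clock genes rose in 15 of 18, with a median of 0.76 (camera adjusted p = 0.00674, and adjusted p = 0.116 with an estimated correlation). Nr1d1, a clock repressor gene, had 2.33 ± 0.11. Leptin, insulin and cytokine receptor signalling rose in 13 of 20 and fell in 6, with a median of 1.06 (camera adjusted p = 0.0394, and adjusted p = 0.304 with an estimated correlation), with Stat3 at 2.07 ± 0.06 and Lifr at 2.75 ± 0.10.

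Lower in the pull-down were 70 of 79 cytosolic ribosomal protein genes, with a median of −0.60 (camera adjusted p = 5.52e-07, and adjusted p = 0.333 with an estimated correlation). Rpl26 had −1.49 ± 0.07. All 9 genes of neurons that carry gonadal steroid feedback fell, with a median of −2.74 (camera adjusted p = 0.000234, and adjusted p = 0.122 with an estimated correlation). Members were Tacr3 (−3.55 ± 0.16), Pgr (−3.42 ± 0.15) and Prlr (−2.74 ± 0.12). Of 14 heat shock protein genes 9 fell and 3 rose, with a median of −0.84 (camera adjusted p = 0.0316, and adjusted p = 0.226 with an estimated correlation). Hsph1 had −2.01 ± 0.06 and Bag3, a co-chaperone gene, 2.11 ± 0.08. The remaining 6 function lists did not pass: glycolysis (median 0.24, adjusted p = 0.138, and 0.567 with an estimated correlation), androgen response (0.34, adjusted p = 0.17, and 0.413), steroid receptors and metabolism (1.34, adjusted p = 0.185, and 0.318), immediate early genes (−0.35, adjusted p = 0.457, and 0.725), oxidative phosphorylation (0.09, adjusted p = 0.55, and 0.88) and the unfolded protein response (−0.07, adjusted p = 0.868, and 0.88).

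The effect of the diet was taken between sham mice on HFD and on chow. In the pull-down (6 libraries on HFD and 7 on chow), Tmc7 (log2 fold change 0.43 ± 0.10, SE) and Safb (0.38 ± 0.10) were among the genes nearest to a call upwards, and Rpusd1 (−0.37 ± 0.11), Hopx (−0.60 ± 0.18) and Mat2a (−0.39 ± 0.12) downwards; none of these passed with edgeR, with an unadjusted p of 0.000176 for Tmc7 and an adjusted p of 1.00 for each. No gene passed with edgeR, of 14059 tested and 240 at an unadjusted p under 0.05; DESeq2 called 2 and limma voom 0. Pomc had a log2 fold change of 0.93 ± 0.38, Npy −0.48 ± 0.23, Agrp −0.48 ± 0.66, Esr1 0.37 ± 0.27, Gfap −0.15 ± 0.13 and Aldh1l1 0.02 ± 0.11, none past the threshold with edgeR. Single pull-downs weigh on the first 3: HFD sample 1 had 73.9 CPM of Pomc (others 18.1 to 28.6), and chow sample 8 had 6.22 CPM of Agrp (0.387 to 0.783) and 12.5 CPM of Npy (4.18 to 6.75). Without the 4 pull-downs rich in Gm42418, Pomc had 0.60 and Npy −0.36.

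Cholesterol synthesis genes lay lower on HFD in 21 of 24 cases, with a median of −0.15 (camera adjusted p = 0.00334, and adjusted p = 0.974 with an estimated correlation). Members were Fdft1 (−0.25 ± 0.12), Msmo1 (−0.21 ± 0.10) and Sqle (−0.18 ± 0.11). Oxidative phosphorylation genes lay lower in 38 of 39 cases, with a median of −0.08 (camera adjusted p = 0.00334, and adjusted p = 0.974 with an estimated correlation). Cox5a had −0.12 ± 0.07. In both lists 0 members passed, over all genes by edgeR and adjusted over the list alone. Without the 4 pull-downs rich in Gm42418, 0 lists passed.

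Orchiectomy was compared on HFD. In the pull-down of orchiectomised mice, Tac2, the neurokinin B gene of steroid-feedback neurons, had 7.22 ± 4.08 CPM (n = 7) against 1.16 ± 0.729 CPM in sham mice (n = 6), a log2 fold change of 2.65 ± 0.44 (SE) with an edgeR adjusted p of 0.0579. Esr1 had 3.17 ± 0.862 against 1.24 ± 0.461 CPM (1.36 ± 0.26, adjusted p = 0.103), with no overlap between the groups. Cacng4, a subunit that regulates AMPA receptors, had 29.1 ± 2.97 against 41.5 ± 4.75 CPM (−0.51 ± 0.09, adjusted p = 0.0594). Cyp4f15, a cytochrome P450 of fatty acids, had 30.2 ± 3.39 against 47.2 ± 8.54 CPM (−0.64 ± 0.13, adjusted p = 0.103), again without overlap. Groups without overlap were found for 20 of the 14059 genes tested. A gene unrelated to the groups parts 7 from 6 libraries fully with a probability of 0.00117, the smallest exact permutation p. Chance thus gives a number of this order, and lack of overlap does not set these genes apart. Wee1 (0.90 ± 0.20, adjusted p = 0.246), Nrf1 (0.53 ± 0.12, adjusted p = 0.292) and Xbp1 (0.62 ± 0.15, adjusted p = 0.559) were nearest to a call upwards with at least 5 CPM. None of these passed with edgeR.

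With edgeR, 0 of 14059 genes passed and 918 had an unadjusted p under 0.05; DESeq2 called 10 and limma voom 79. Without the 4 pull-downs rich in Gm42418 edgeR called 4 genes, Tac2, Esr1, Sult1a1 and Phyhd1, the last being outside the naming rule and named after its value was seen. Aldh1l1 (−0.06 ± 0.11), Gfap (0.14 ± 0.13), Agrp (−0.75 ± 0.71), Npy (0.19 ± 0.23) and Pomc (0.44 ± 0.38) did not pass.

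Of 35 lists, 14 passed camera with its preset correlation, 0 with an estimated one and 0 with fry. Genes of steroid-feedback neurons were higher in the pull-down after orchiectomy in 7 of 8 cases, with a median of 0.70 (camera adjusted p = 9.68e-06, and adjusted p = 0.253 with an estimated correlation); 0 passed over all genes and 5 rose when adjusted over the list alone, among them Tac2, Esr1, Prlr (0.76 ± 0.27) and Pdyn (0.64 ± 0.23). Steroid receptors and metabolism were higher in 11 of 16 cases, with a median of 0.12 (camera adjusted p = 0.0235, and adjusted p = 0.253 with an estimated correlation), and 2 rose when adjusted over the list alone, led by Esr1 and Nr3c2, the mineralocorticoid receptor (0.55 ± 0.15). The androgen response list did not pass (median 0.04, camera adjusted p = 0.128, and adjusted p = 0.552 with an estimated correlation). Immediate early genes were higher in 13 of 16 cases, with a median of 0.36 (camera adjusted p = 0.000386, and adjusted p = 0.278 with an estimated correlation). Among these were Nr4a1 (0.89 ± 0.25), the 1 member that passed when adjusted over the list alone, and Klf2 (1.33 ± 0.48). Astrocyte reactivity was higher in 21 of 27 cases, with a median of 0.32 (camera adjusted p = 0.00144, and adjusted p = 0.449 with an estimated correlation), with 4 members past the threshold adjusted over the list alone, such as S100a10 (0.56 ± 0.16) and Vim (0.42 ± 0.14). Class I antigen presentation was higher in 12 of 14, with a median of 0.33 (camera adjusted p = 0.00123, and adjusted p = 0.449 with an estimated correlation). Psmb9, an immunoproteasome subunit gene, had 0.96 ± 0.34. The unfolded protein response was higher in 15 of 19, with a median of 0.20 (camera adjusted p = 0.00878, and adjusted p = 0.253 with an estimated correlation), with Xbp1 the 1 member to rise when adjusted over the list alone. NF-kB and cytokine genes were higher in 13 of 16, with a median of 0.23 (camera adjusted p = 0.0475, and adjusted p = 0.253 with an estimated correlation). Markers of endothelial cells were higher in the same comparison, as given below, so these lists do not show in which cells their genes rose.

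Ribosomal protein genes were lower after orchiectomy in 69 of 79 cases, with a median of −0.14 (camera adjusted p = 3.33e-06, and adjusted p = 0.61 with an estimated correlation), and oxidative phosphorylation genes in 32 of 39, with a median of −0.11 (camera adjusted p = 0.00032, and adjusted p = 0.61 with an estimated correlation). Fatty acid oxidation was lower in 16 of 21 cases, with a median of −0.13 (camera adjusted p = 0.002, and adjusted p = 0.449 with an estimated correlation). Acaa2, one of its genes, had −0.26 ± 0.08. Astrocyte markers were lower in 19 of 22, with a median of −0.12 (camera adjusted p = 0.00343, and adjusted p = 0.593 with an estimated correlation), Aldoc (−0.31 ± 0.08) falling when adjusted over the list alone and Aqp4 at 0.32 ± 0.11. Glucocorticoid response genes were lower in 12 of 16, with a median of −0.23 (camera adjusted p = 0.0261, and adjusted p = 0.479 with an estimated correlation), where Sult1a1, a sulfotransferase (−1.34 ± 0.28), fell when adjusted over the list alone. Markers of other cells were higher: endothelial markers in 13 of 13 cases, with a median of 0.78 (camera adjusted p = 1.09e-05, and adjusted p = 0.479 with an estimated correlation). Ly6c1 had 1.27 ± 0.49 and Itm2a 1.26 ± 0.48. The rise lay in 3 of 7 pull-downs, samples 6, 11 and 22 with means of 6.38, 6.21 and 6.76 log2 CPM, while the other 4 had 4.64 to 4.99 and sham mice 4.78 on average (exact permutation p = 0.138). Sham HFD sample 1 was also high, at 6.16, against 4.24 to 4.97 in the other sham HFD pull-downs. Oligodendrocyte markers were higher in 13 of 14 cases, with a median of 0.25 (camera adjusted p = 0.0365, and adjusted p = 0.668 with an estimated correlation). Across the pull-downs, the mean of the endothelial markers rose with log2 CPM of Gm42418 (r = 0.749, permutation p = 0.00022, adjusted p = 0.000293; rho = 0.635, permutation p = 0.00295, adjusted p = 0.00393; 20 samples, 4 relations), and without the 2 samples farthest from the median r was 0.652 and rho 0.525 (permutation p = 0.0267).

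Orchiectomised mice on HFD were also set against sham mice on chow, a comparison that joins diet and operation. In the pull-down, 2 genes rose: Tac2 on chromosome 10 (127724478 to 127731768, GRCm38), from 0.886 ± 0.358 to 7.22 ± 4.08 CPM, a log2 fold change of 3.03 ± 0.43 (SE), and Esr1, also on chromosome 10 (4611593 to 5005614), from 0.946 ± 0.243 to 3.17 ± 0.862 CPM, a log2 fold change of 1.73 ± 0.25. Each had an edgeR adjusted p of 0.00312 and no overlap between the 7 libraries of either group. They were the 2 genes called of 14059 tested, with 1566 at an unadjusted p under 0.05 and 37 with groups that did not overlap. DESeq2 called 8 and limma voom 11. Both genes were scarce in the pull-down and more abundant in the supernatant, where Tac2 had 33.2 ± 5.7 CPM on chow and 32.8 ± 15.0 CPM after orchiectomy. Esr1 had 8.5 ± 1.21 and 8.35 ± 2.09 CPM there. With a filter at a mean of 5 CPM, 0 genes were called, since neither is then tested.

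**Figure D2:**
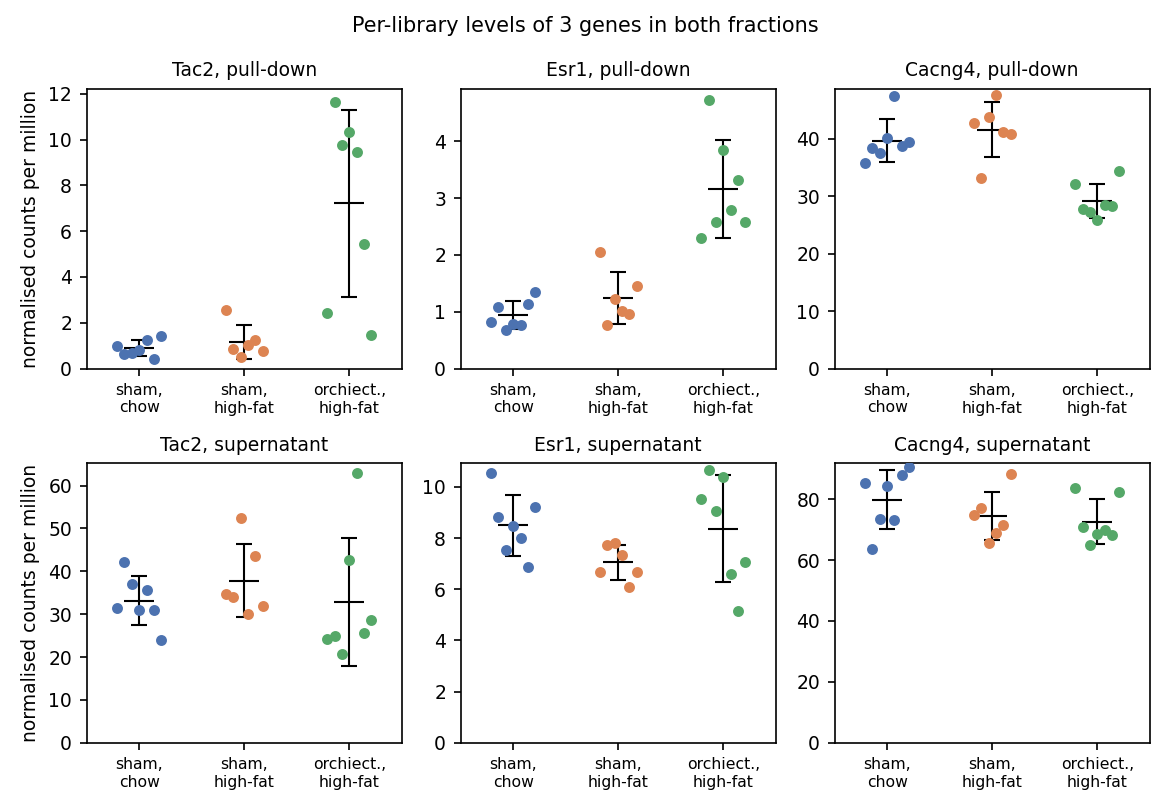
Normalised CPM per library (vertical axes) of Tac2, Esr1 and Cacng4 in pull-down and supernatant for the 3 treatment groups, 6 or 7 libraries each; points are libraries and bars are mean ± SD. In the pull-down, Tac2 reached 7.22 ± 4.08 CPM and Esr1 3.17 ± 0.862 CPM after orchiectomy, above every library of the chow group.

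Other genes near a call in the pull-down were Stk24 (0.57 ± 0.12, adjusted p = 0.183), Axin2 (0.74 ± 0.17, adjusted p = 0.255), Ldb1 (0.53 ± 0.12, adjusted p = 0.26), Cacng4 (−0.44 ± 0.09, adjusted p = 0.121), N4bp2l1 (−0.39 ± 0.08, adjusted p = 0.242) and Fah (−0.40 ± 0.10, adjusted p = 0.369), none of which passed with edgeR. Cacng4 passed in 4 of 15 alternative fits, and Stk24 and Axin2 in 3 each. Pomc had 42.1 ± 26 CPM after orchiectomy and 16.2 ± 6.01 CPM on chow, with 31.1 ± 21.3 CPM in sham mice on HFD, and its log2 fold change of 1.37 ± 0.37 did not pass with edgeR (adjusted p = 0.369) but did in 2 of 15 alternative fits. Agrp (−1.23 ± 0.67), Npy (−0.29 ± 0.22), Aldh1l1 (−0.04 ± 0.11) and Gfap (−0.01 ± 0.13) did not pass either, and the sign for Gfap, close to 0, turned in 6 alternative fits. The value for Agrp leans on 1 chow pull-down with 6.22 CPM, against 0.387 to 0.783 CPM in the other 6.

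Genes of steroid-feedback neurons were higher than on chow with a median of 0.55 (camera adjusted p = 2.41e-05, and adjusted p = 0.301 with an estimated correlation); 2 rose over all genes and 5 when adjusted over the list alone, including Tacr3, the neurokinin B receptor gene (1.13 ± 0.38). Steroid receptors and metabolism had a median of 0.15 (camera adjusted p = 0.0135, and adjusted p = 0.301 with an estimated correlation), with 1 rising over all genes and 4 when adjusted over the list alone, among them Akr1c14, which reduces steroids (1.17 ± 0.36). The directional test fry called these 2 lists and no other (adjusted p = 0.0281 for both). Esr1 stands in both lists, so the 2 calls are not independent of each other or of the call of Esr1 itself. Immediate early genes had a median of 0.32 (camera adjusted p = 0.00219, and adjusted p = 0.367 with an estimated correlation), and 3 rose when adjusted over the list alone, such as Fos (0.61 ± 0.17). Leptin, insulin and cytokine receptor signalling had a median of 0.13 (camera adjusted p = 0.0135, and adjusted p = 0.301 with an estimated correlation), the unfolded protein response 0.09 (camera adjusted p = 0.0368, and adjusted p = 0.301 with an estimated correlation), with 2 rising when adjusted over the list alone, and astrocyte reactivity 0.25 (camera adjusted p = 0.048, and adjusted p = 0.548 with an estimated correlation). Markers of endothelial cells (1.10, camera adjusted p = 1.35e-06, and adjusted p = 0.463 with an estimated correlation) and oligodendrocytes (0.39, camera adjusted p = 0.0379, and adjusted p = 0.548 with an estimated correlation) were higher as well. The mean of the endothelial markers was 5.49 log2 CPM after orchiectomy and 4.64 on chow (exact permutation p = 0.0705).

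Lower than on chow were ribosomal protein genes in 74 of 79 cases, with a median of −0.17 (camera adjusted p = 1.32e-09, and adjusted p = 0.494 with an estimated correlation), and oxidative phosphorylation genes in 38 of 39, with a median of −0.18 (camera adjusted p = 3.57e-09, and adjusted p = 0.463 with an estimated correlation). Antioxidant and metallothionein genes had a median of −0.13 (camera adjusted p = 0.0368, and adjusted p = 0.494 with an estimated correlation), with 3 falling and 1 rising when adjusted over the list alone, and glucocorticoid response genes −0.18 (camera adjusted p = 0.0399, and adjusted p = 0.494 with an estimated correlation), with 3 falling when adjusted over the list alone. Mt2, a metallothionein in both lists, had −0.58 ± 0.17. Fatty acid oxidation (−0.17, camera adjusted p = 0.0368, and adjusted p = 0.544 with an estimated correlation), cholesterol synthesis (−0.10, camera adjusted p = 0.0368, and adjusted p = 0.548 with an estimated correlation) and astrocyte markers (−0.10, camera adjusted p = 0.0368, and adjusted p = 0.548 with an estimated correlation) were lower too. Without the 4 pull-downs rich in Gm42418, 7 lists passed in place of 15.

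In the supernatant, edgeR called no gene for any of these comparisons, while DESeq2 called 3 for diet, 5 for orchiectomy and 3 for both. For diet, Pold2, a DNA polymerase subunit (0.56 ± 0.14), Olfml3 (0.40 ± 0.12) and Serpina3n (0.49 ± 0.15) were nearest to a call upwards and Sptbn4 (−0.41 ± 0.13), Gfm2 (−0.42 ± 0.15) and Vegfa (−0.44 ± 0.16) downwards, each with an edgeR adjusted p of 0.904. With edgeR no gene of 14628 passed and 206 had an unadjusted p under 0.05; DESeq2 called 3 and limma voom 0. Pomc had 0.64 ± 0.25, Aldh1l1 0.46 ± 0.57, Gfap 0.33 ± 0.28, Esr1 −0.27 ± 0.15, Agrp 0.21 ± 0.25 and Npy 0.01 ± 0.16, none past the threshold with edgeR. The sign for Npy turned in alternative fits, to −0.18 with mt-Rnr2 as a covariate. Oxidative phosphorylation was higher on HFD in 35 of 39 cases, with a median of 0.14 (camera adjusted p = 9.47e-06, and adjusted p = 0.892 with an estimated correlation), ribosomal protein genes in 66 of 79, with a median of 0.08 (camera adjusted p = 0.000762, and adjusted p = 0.892 with an estimated correlation), glycolysis in 19 of 20, with a median of 0.15 (camera adjusted p = 0.00201, and adjusted p = 0.892 with an estimated correlation), and astrocyte markers in 19 of 22, with a median of 0.22 (camera adjusted p = 0.0442, and adjusted p = 0.892 with an estimated correlation).

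After orchiectomy on HFD, Sytl4, a granule docking protein gene on the X chromosome (133936385 to 133981812), had 11.4 ± 1.77 CPM in the supernatant (n = 7) against 19.9 ± 3.51 CPM in sham mice (n = 6), a log2 fold change of −0.81 ± 0.15 (SE) with an edgeR adjusted p of 0.292. Cited1, a transcriptional co-regulator also on X, had 16.8 ± 1.56 against 26.1 ± 5.02 CPM (−0.63 ± 0.13, adjusted p = 0.365). Neither gene passed with edgeR, and DESeq2 called both. The groups did not overlap for either gene, as for 14 of the 14628 genes tested. At a probability of 0.00117 per gene, the smallest exact permutation p for 7 against 6, chance gives a number of this order. Lack of overlap thus does not set these genes apart. Lamp5 (−0.66 ± 0.18), Serpinb1a (0.55 ± 0.13), Vegfa (0.56 ± 0.16) and Car2 (0.32 ± 0.10) had an adjusted p of 0.945. No gene of 14628 passed with edgeR and 439 had an unadjusted p under 0.05; DESeq2 called 5 and limma voom 1. Against sham mice on chow, Sytl4 had −0.82 ± 0.15 (adjusted p = 0.157), Lamp5 −0.55 ± 0.17, Irs4 −0.36 ± 0.12, Mpzl1 0.34 ± 0.09, Sh3pxd2b 0.71 ± 0.20 and Pex11a 0.37 ± 0.11, and no gene passed with edgeR, 331 having an unadjusted p under 0.05; DESeq2 called 3 and limma voom 0. Agrp had −0.68 ± 0.26 against sham mice on HFD and −0.47 ± 0.25 against chow, Pomc −0.30 ± 0.25 and 0.34 ± 0.24, Npy −0.19 ± 0.16 and −0.18 ± 0.16, Esr1 0.24 ± 0.15 and −0.02 ± 0.15, Gfap 0.19 ± 0.28 and 0.52 ± 0.27, and Aldh1l1 0.19 ± 0.56 and 0.65 ± 0.55, none past the threshold. The sign for Esr1 against chow and that for Aldh1l1 against HFD turned with the total count as a covariate, to 0.070 and −0.028.

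Astrocyte markers were higher in the supernatant of orchiectomised mice in 22 of 22 cases, with a median of 0.35 against sham mice on HFD (camera adjusted p = 0.00208, and adjusted p = 0.736 with an estimated correlation) and 0.60 against chow (camera adjusted p = 3.39e-12, and adjusted p = 0.594 with an estimated correlation). Transmitter and ion homeostasis genes had medians of 0.32 (camera adjusted p = 0.00298, and adjusted p = 0.736 with an estimated correlation) and 0.40 (camera adjusted p = 1.52e-06, and adjusted p = 0.706 with an estimated correlation). Against sham mice on HFD, extracellular matrix genes were higher in 18 of 20 cases, with a median of 0.21 (camera adjusted p = 0.00208, and adjusted p = 0.612 with an estimated correlation). The members with the smallest p included Lama2 (0.57 ± 0.18) and Hapln1 (0.63 ± 0.21). Lower were oxidative phosphorylation (median −0.11, camera adjusted p = 0.000132, and adjusted p = 0.736 with an estimated correlation), ribosomal protein genes (−0.07, camera adjusted p = 0.000147, and adjusted p = 0.736 with an estimated correlation), neuropeptides (−0.15, camera adjusted p = 0.00422, and adjusted p = 0.736 with an estimated correlation) and the glucocorticoid response (−0.06, camera adjusted p = 0.0208, and adjusted p = 0.612 with an estimated correlation). Of the last, Plin4, a lipid droplet coat gene (−1.60 ± 0.35), fell when adjusted over the list alone. Against chow, genes of steroid-feedback neurons were lower in 8 of 9 cases, with a median of −0.13 (camera adjusted p = 0.0266, and adjusted p = 0.419 with an estimated correlation), and hypoxia genes higher in 15 of 18, with a median of 0.09 (camera adjusted p = 0.0355, and adjusted p = 0.587 with an estimated correlation). In these supernatant lists 0 members passed over all genes tested, with edgeR. Without the supernatant of orchiectomised sample 2, 12 lists passed against chow in place of 4, in a fit chosen after seeing the data.

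The astrocyte markers left in a supernatant followed the pull-down of the same sample number. Across the 20 samples their mean log2 CPM rose with log2 CPM of Gm42418 in the pull-down (r = 0.855, permutation p = 1e-05, the smallest the resampling can give, adjusted p = 2e-05; rho = 0.85, permutation p = 2e-05, adjusted p = 8e-05). Without the 2 samples farthest from the median, r was 0.807, and after subtracting the group means it was 0.844.

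**Figure D3:**
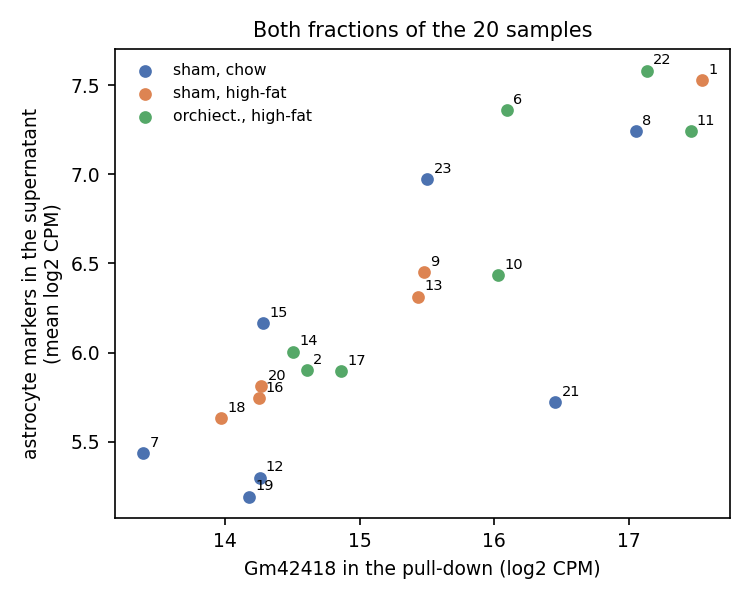
Mean log2 CPM of the astrocyte markers in the supernatant (vertical axis) against log2 CPM of Gm42418 in the pull-down (horizontal axis) for the 20 samples, labelled by sample number and coloured by treatment group. The points rise together, with r = 0.855, and the treatment groups lie among one another.

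Whether an effect differed between the fractions was tested by interaction. For orchiectomy on HFD, Tac2 rose more in the pull-down than in the supernatant, by a log2 difference of 2.84 ± 0.48 (SE, edgeR adjusted p = 0.00978), and was the 1 gene called of 15629, with 692 at an unadjusted p under 0.05. With the sample number as a block, the difference was 2.76 with an adjusted p of 0.176 and 0 genes passed; over the alternatives its adjusted p lay between 4.31e-05 and 0.272. Esr1 had a difference of 1.11 ± 0.27 (adjusted p = 0.752), Pomc 0.72 ± 0.46, Npy 0.38 ± 0.28, Agrp −0.08 ± 0.69, Gfap −0.07 ± 0.31 and Aldh1l1 −0.27 ± 0.53, none past the threshold with edgeR, although limma voom called Esr1. For diet, Ttll3 (0.97 ± 0.27), Cbwd1 (0.79 ± 0.25) and Oxsr1 (1.04 ± 0.33) were nearest upwards and Rpusd1 (−0.63 ± 0.18), Gpr62 (−0.78 ± 0.24) and Pold2 (−0.65 ± 0.20) downwards, each with an adjusted p of 0.97. No gene passed there with edgeR and 399 had an unadjusted p under 0.05; DESeq2 called 4 and limma voom 0, and for orchiectomy they called 5 and 6. Esr1 (0.64 ± 0.29), Pomc (0.30 ± 0.47), Agrp (−0.69 ± 0.71), Npy (−0.49 ± 0.28), Gfap (−0.48 ± 0.32) and Aldh1l1 (−0.44 ± 0.55) did not pass for diet.

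Finally, the effects of diet and of orchiectomy were related across genes, to see whether genes moved by the diet moved back after orchiectomy. Both use the 6 sham HFD libraries, which alone pull the correlation below 0, and genes are not independent replicates. In the pull-down, r was −0.264 and rho −0.179 over 14059 genes, against −0.523 on average for simulated unchanged groups (95% of 1000 simulations between −0.813 and −0.112). The covariance was −0.0127 against a simulated −0.031. In the supernatant, r was −0.663 and rho −0.634 over 14628 genes, against −0.522 in simulations (between −0.854 and 0.0379), and the covariance was −0.0334 against −0.0319. Both lay within the simulated ranges. With the HFD libraries split into 3 and 3, so that no library was shared, r averaged 0.139 over 20 splits in the pull-down (from −0.145 to 0.482) and −0.0775 in the supernatant (from −0.291 to 0.323). For simulated unchanged groups split in this way, 95% of r lay between −0.481 and 0.456 in the pull-down. In the supernatant the range was −0.584 to 0.613. Both averages lay inside.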

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

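The 3 tests that weigh the change of Tac2 and Esr1, and the fits without 4 pull-downs, were chosen only after the result was seen.

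Tac2 was flagged because its change with orchiectomy on HFD differed between the fractions, in the fit that takes the 2 fractions of a sample as independent. The log2 difference was 2.84 ± 0.48 with edgeR (adjusted p = 0.00978). With the sample number as a block the adjusted p was 0.176, and over the 11 alternatives it lay between 4.31e-05 and 0.272. In the pull-down, Tac2 and Esr1 were also the genes called between orchiectomised mice on HFD and sham mice on chow, with log2 fold changes of 3.03 ± 0.43 and 1.73 ± 0.25.

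If neuron RNA of unchanged make-up had been carried into the pull-downs of orchiectomised mice, the 21 neuron markers would have risen about as far as these genes, but their median log2 fold change was 0.15 and the highest was 0.58. Their mean per library differed by 0.15 ± 0.22 (SE over 7 and 7 libraries) in log2 CPM. If those dissections had held more tissue with Tac2 neurons, Tac2 would have been higher in the supernatant too, where its log2 fold change was −0.0143 ± 0.207. Without the 4 pull-downs rich in Gm42418 both genes still passed (3.07 and 1.67, higher adjusted p 0.0110), so these libraries alone do not account for the change. What stays open, and was not tested, is RNA of a few neuron kinds carried over selectively and a change in astrocytes that express these genes; either may lie behind the pattern. Diet and loss of the testes are joined in this comparison. Against sham mice on HFD, Tac2 had 2.65 ± 0.44 (edgeR adjusted p = 0.0579) and Esr1 1.36 ± 0.26 (adjusted p = 0.103); neither passed there, while Tac2 passed in 6 and Esr1 in 5 of 14 alternative fits.

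Among 162 groups of 6 or 7 libraries and measures, 24 held a library far from the rest, where chance gives about 1 in 20, or 8.1. The pull-down of sham HFD sample 1 was such a library in 11 measures. It had 18.2% of its counts in Gm42418 (others 1.60% to 4.54%), 27.8% in its 10 most abundant genes (15.8% to 17.4%), 1.32% in mitochondrial genes (0.702% to 0.798%) and 0.412% in mt-Rnr2 (0.175% to 0.231%). Its first principal component was 50.02 (−23.8 to 0.68). Its mean log2 CPM was 10.67 for astrocyte markers (10.87 to 10.95), 5.44 for neuron markers (4.49 to 4.62), 3.61 for neuropeptides (2.16 to 2.67) and 3.68 for mural cell markers (2.31 to 2.73). It had 73.9 CPM of Pomc (18.1 to 28.6) and 2.56 CPM of Tac2 (0.521 to 1.24). The supernatant of this sample held 16.5 CPM of Aldh1l1, against 1.83 to 5.73 in the others.

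The pull-down of orchiectomised sample 22 had 1.63% of its counts in mitochondrial genes (others 0.643% to 1.01%), 0.544% in mt-Rnr2 (0.183% to 0.297%) and 96.4 CPM of Pomc (21.3 to 52.4). Its mean log2 CPM was 10.44 for astrocyte markers (10.7 to 10.9) and 3.59 for oligodendrocyte precursor markers (2.75 to 3.08). The pull-down of chow sample 8 had 0.336% of its counts in mt-Rnr2 (0.181% to 0.229%), 6.22 CPM of Agrp (0.387 to 0.783) and 12.5 CPM of Npy (4.18 to 6.75). These 3 pull-downs are among the 4 with over 10% of their counts in Gm42418.

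The pull-down of sham HFD sample 20 held 20792147 counts, against 10227859 to 11874053 in the others. In the supernatant of orchiectomised sample 2, Lrrc17 took 0.495% of the counts, against 3.65% to 4.89% in the others. The supernatant of orchiectomised sample 6 had a mean of 10.3 log2 CPM for red blood cell markers (7.04 to 8.06). The supernatant of chow sample 19 had 41.4 CPM of Npy (28.5 to 32.9).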

How the results depend on the processing

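The fits without the 4 pull-downs rich in Gm42418, without the supernatant of orchiectomised sample 2, and with covariates for Gm42418 or mt-Rnr2, as well as the neuron marker covariate for lists, were chosen after seeing the data. Of the fits of single named genes under each alternative, 4943 kept direction and side of the threshold, 56 newly passed, 7 no longer passed and 22 changed sign. The cause of the changes below was not tested unless stated.

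Between the fractions, counts of called genes stayed within 1.5 times of 13561 (DESeq2 16646, limma voom 13857, DESeq2 size factors 13530, no filter 17938, mean of at least 5 CPM 9600, TPM-named signal 11914, 11904 and 17034, without 4 pull-downs 13702), apart from 6695 with glmTreat, which asks for more than a 2-fold change. Against the main fit, the median of all genes shifted by −0.29 with DESeq2 and by −0.17 with no filter, the only scalings or filters that moved it by over 0.1. Both of these fits kept genes with low counts, so their medians are over more genes and do not by themselves show a change of scaling. With the sample number as a replicate block, 13485 genes and 24 lists passed between the fractions and 0 in the diet interaction; the block changed the call in the orchiectomy interaction alone, from 1 gene to 0.

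In simulated counts for orchiectomy in the pull-down, 21 of 179 calls by DESeq2 were false, against 9 of 155 by edgeR. In the pull-down, DESeq2 called 2, 10 and 8 genes for diet, orchiectomy and both together, limma voom 79 for orchiectomy and 11 for both, the fit of all 40 libraries 6 and 6, the neuron marker covariate 3 and 7, and the Gm42418 covariate 2 for orchiectomy. For orchiectomy, 4 genes passed without the 4 pull-downs. For both together, a mean of at least 5 CPM gave 0, because Tac2 and Esr1 are then not tested, and log2 of the TPM-named signal plus 1 without a filter gave 1. The adjusted p of Tac2 there ran from 1.21e-08 to 0.0553 and that of Esr1 from 1.13e-06 to 0.0169. In the supernatant, DESeq2 called 3, 5 and 3 genes, limma voom 1 for orchiectomy, the fit of all 40 libraries 1 for orchiectomy and 1 for both, and the mt-Rnr2 covariate 1 for both. In the interactions, DESeq2 called 4 for diet and 5 for orchiectomy, limma voom 6 for orchiectomy, the fit without 4 pull-downs 2, and the 3 tests of the TPM-named signal 0, 0 and 0.

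Of the lists, 0 passed with an estimated correlation in each of the 7 comparisons. With fry, 0 passed for diet, 0 for orchiectomy and 2 for both in the pull-down, and 0, 0 and 0 in the supernatant. For diet 0 and for both 7 passed without the 4 pull-downs, and without the supernatant of orchiectomised sample 2, 12 passed for both there in place of 4. The relation of the diet and orchiectomy effects turned to 0.139 in the pull-down and moved to −0.0775 in the supernatant when the HFD libraries were split, which removes the shared libraries. Both averages lay within the ranges simulated for unchanged groups split in this way.

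Some signs of log2 fold changes turned. Without the 4 pull-downs, Pomc between the fractions had −0.17, Gfap for both 0.062, Gfap in the orchiectomy interaction 0.038, and in the diet interaction Agrp went from −0.69 to 0.46 and Pomc from 0.30 to −0.077. With limma voom, Gfap for both had 0.0028, Npy for diet in the supernatant −0.061 and Esr1 for both there 0.0080. Gfap for both had 0.0013 with the neuron marker covariate and 0.0069, 0.0069 and 0.0069 in the 3 tests of the TPM-named signal. Npy for diet in the supernatant had −0.0096, −0.011 and −0.0096 in these 3 tests, −0.0032 without mitochondrial genes and −0.18 with mt-Rnr2. With the total count as a covariate, Aldh1l1 for orchiectomy in the supernatant had −0.028 and Esr1 for both 0.070, and without the supernatant of orchiectomised sample 2 Esr1 had 0.018. Agrp in the orchiectomy interaction had 0.11 in both tests of the TPM-named signal plus 1.

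With 6 or 7 libraries per group, simulated 2-fold changes were found in 67.2% to 89.6% of genes in the pull-down and 65.7% to 82.1% in the supernatant. There, 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold at once. The real treatment fits called 0 to 2 genes, so their threshold was stricter and a lone 2-fold change would be found less often. Genes near 1 CPM, such as Esr1 in the pull-down, rest on few reads per library.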

Other observations

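The test of paired fractions, that of estimated correlations and the fit without 1 supernatant below were chosen only after the result was seen, while the Gm42418 covariate test and the splits of the samples were stated before their results, the former as an alternative added after seeing the data.

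Several genes passed in some fits of a comparison and not in others. After orchiectomy on HFD, Tac2 was higher in the pull-down in all 14 alternative fits, with log2 fold changes from 1.73 to 2.91, and passed in 6 of them (adjusted p from 1.69e-05 to 0.321). Esr1 lay between 0.87 and 1.48 and passed in 5 of 14 (0.000625 to 0.365). Cacng4 was lower there in all 15 alternative fits, with log2 fold changes from −0.56 to −0.48, and passed in 5 of them (adjusted p from 0.000387 to 0.321). Cyp4f15 lay between −0.66 and −0.56 and passed in 2 of 15 (adjusted p from 0.00399 to 0.587), and Sult1a1 between −1.40 and −1.11, passing in 4 of 15 (0.00363 to 0.765). Wee1, a kinase that holds back mitosis, lay between 0.70 and 0.94 and passed in 2 of 15 (0.00586 to 0.765).

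In the supernatant, Sytl4 was lower after orchiectomy in all 14 alternative fits of each comparison. Against sham mice on HFD it lay between −0.81 and −0.65 and passed in 2 fits (adjusted p from 0.00217 to 0.994), and against chow it lay between −0.82 and −0.67 and passed in 3 (0.000815 to 1.00). Its level was 20 ± 4.47 CPM on chow, 19.9 ± 3.51 CPM on HFD and 11.4 ± 1.77 CPM after orchiectomy. Pomc in the pull-down was higher after orchiectomy than on chow by 0.97 to 1.39 in 15 alternative fits and passed in 2 (0.00334 to 0.532).

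Astrocyte markers were higher in the supernatant of orchiectomised mice with the preset correlation of camera, but not with an estimated one (adjusted p = 0.736 against sham mice on HFD and 0.594 against chow). Their mean per library did not pass either (exact permutation p = 0.367 and 0.155). A candidate explanation is that a pull-down which took less of the tagged ribosomes left more astrocyte RNA behind and held relatively more Gm42418. However, Gm42418 took a larger share of the counts in the pull-downs (mean 5.99%) than in the supernatants (mean 1.49%). It is therefore no direct measure of RNA carried over from other cells. Over the 20 sample numbers, Gm42418 in the pull-down and the astrocyte markers in the supernatant had r = 0.855 (permutation p = 1e-05, the smallest the resampling can give, adjusted p = 2e-05), and 0.844 after subtracting the group means. Neuron markers in the pull-down also rose with the astrocyte markers left behind (r = 0.827, permutation p = 1e-05, adjusted p = 2e-05; rho = 0.711, permutation p = 0.00077) and with Gm42418 (r = 0.712, permutation p = 0.00038; rho = 0.602, permutation p = 0.00608), and without the 2 farthest samples r was 0.751 and 0.641, and rho 0.604 (permutation p = 0.00925) and 0.463 (permutation p = 0.0548), so the rank relation with Gm42418 no longer passes. With Gm42418 as a covariate, the median of the astrocyte markers went from 0.60 to 0.13 against chow (camera adjusted p = 0.00125) and from 0.35 to 0.06 against sham mice on HFD (camera adjusted p = 0.558); an effect of orchiectomy on what the pull-down takes stays open.

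In the pull-down after orchiectomy on HFD, endothelial markers were higher and ribosomal protein and oxidative phosphorylation genes lower. With Gm42418 as a covariate the 3 lists still passed (highest camera adjusted p = 0.0178), but the shares of their medians kept were 0.67, 0.31 and 0.451. Gm42418 was richer in the pull-downs than in the supernatants, so it is no plain measure of RNA that is not from astrocytes. A shared rise of such RNA therefore cannot be told apart from another cause. With an estimated correlation the lowest camera adjusted p of the 3 lists was 0.479. This cannot decide whether genes of a list that vary together between samples lie behind the result, since no list passed this way in any comparison. Between the fractions, where all astrocyte markers rose, the lowest such adjusted p of any list was 0.116. Regroupings of the real samples bear on the question. For orchiectomy in the pull-down, the preset correlation called a median of 8 lists in them, and 21 of 100 splits gave at least 14. In simulated counts with independent genes, 1 of 34 unchanged lists was called. Preset camera calls like these thus arise without a treatment effect, and their p-values are no firm evidence of one. With the covariate, 12 of the 14 lists passed for orchiectomy on HFD and 6 of 15 against chow in the pull-down, and 4 of 7 and 1 of 4 in the supernatant, where the 4 became 12 without the supernatant of orchiectomised sample 2. No biological explanation of these lists was tested.

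Other splits of the samples into groups of the same sizes, 100 for each comparison with the real one included, show what chance can give. Between the fractions, the splits argue against chance for the genes: 1 split, the real one, called as many as 13561. The highest other called 11180. It exchanged pull-down and supernatant in 4 of the 20 sample numbers and left 16 as they are, or the reverse. For the lists, 4 splits gave as many as 24 (highest other 24), so their count does not exclude chance. The 2 genes called in the pull-down between orchiectomised mice and chow were reached by 1 split, the real one (highest other 0). With 100 splits, 1 is the fewest possible, and several comparisons were split in this way. The splits therefore argue against chance here without excluding it. Chance could not be excluded for the gene called in the orchiectomy interaction, since 7 splits gave at least 1 (highest other 866).

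Where edgeR called 0 genes, 100 of 100 splits necessarily gave as many: the highest other was 0 for diet and 1437 for orchiectomy in the pull-down, 4544 for diet, 0 for orchiectomy and 0 for both together in the supernatant, and 1 in the diet interaction. Nor can chance be excluded for the lists. In the pull-down, 89 splits gave at least 2 lists for diet (highest other 20), 21 at least 14 for orchiectomy (highest other 19) and 12 at least 15 for both (highest other 19). In the supernatant, 77 gave at least 4 for diet (highest other 14), 28 at least 7 for orchiectomy (highest other 12) and 73 at least 4 for both (highest other 15).

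Splits that called many more genes than the real one point to a structure of the samples. The split with 1437 genes, which also gave 866 in the interaction, parted the pull-downs by their first principal component, which holds 32.1% of the variance (means of −16.2 and 29.8, exact permutation p = 0.00117). The split with 4544 genes parted the supernatants by theirs, which holds 41.6% (means of −32.5 and 24.3, exact permutation p = 0.000583). These p-values describe splits picked for their counts.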
